A study of Schmidtea mediterranea with 48 samples.

How the data were processed

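Poly(A) RNA from dissected wound faces of planarian tail fragments was measured by RNA sequencing in 48 libraries, 3 for each of 16 groups. Per the labels, the animals were the asexual strain CIW4 of Schmidtea mediterranea, RNA was taken with TriZOL from 5 wounds per replicate, and libraries were made with the Kapa Stranded mRNA-Seq kit. The labels give 10 feedings with double-stranded RNA over 5 weeks for the myoD experiment and its controls, whereas the series text gives 8 feedings; the 10 of the labels is used as the name of that experiment here. The follistatin (fst) experiment and its controls had 6 feedings over 3 weeks in both sources. Controls received double-stranded RNA of unc-22, a nematode gene. Neither source says whether the wounds of the 3 replicates of a group came from separate sets of animals, so the p-values measure the spread between these samples, which may be technical.

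The submitters' processing notes name CASAVA, cutadapt 1.8, Bowtie 1.1.1, SAMtools and DESeq. Whether strand was used in counting is not given in the sources used here. The deposited table of raw reads holds a count per transcript and library for 26563 transcripts, of which 26280 had a count in at least 1 library; its units are counts, and every value is a whole number. The authors also deposited 20 tables of pairwise comparisons. In these, the authors' group means are a normalised signal, that is, counts divided by size factors and averaged over replicates. The deposited fold changes are a ratio of the second group mean to the first, and the authors' log2 fold change is the log2 of that ratio. The deposited p-value columns hold a p-value and an adjusted p-value per transcript. The means of each of the 16 groups were equal in every deposited table that printed them (largest difference 0). The identifiers are those of a transcript assembly, and 317 of the transcripts share a component number with another one, so reads of related transcripts may have been counted together or apart.

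Counts were analysed in R 4.3.3 with edgeR 4.0.16. The myoD experiment and the follistatin experiment were fitted apart, each with 24 libraries and 1 coefficient per group, after filterByExpr and TMM scaling, with robust quasi-likelihood dispersions and quasi-likelihood F-tests. This left 17527 transcripts in the 10-feeding experiment and 17815 in the 6-feeding experiment. A further fit of all 48 libraries (18230 transcripts) tested the difference between the myoD effect and the fst effect at each time. Whether an RNAi effect varied over time was tested with the interaction terms of an experiment together. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 over all transcripts tested in that comparison. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 8.34% in the 10-feeding fit, 13% in the 6-feeding fit and 10.9% in the joint fit, so equal numbers of calls in the 2 experiments do not mean equal effects. Levels are in CPM, the read count of a transcript scaled to a common library size, as mean and SD over 3 libraries.

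Total counts per library ran from 7169717 to 22065480, with a median of 15946485. Where all libraries of a group held 0 counts of a transcript, the fold is given as a lower bound against a floor of 3 counts over the whole group. With 1 to 3 counts the ratio is given with its 95% exact binomial interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

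The deposited files do not pair identifiers with gene names, and no reference tables were held, so 0 identifiers carry a name. The 12 gene lists fixed beforehand (neoblast, epidermal progenitor, epidermis, muscle, nervous system, gut, protonephridia, cathepsin and pigment cells, wound-induced, anterior position, posterior position, and dorsal-ventral with medial-lateral position) therefore had 0 lists with a member matched and were not tested. The level of the targeted gene in the RNAi libraries could not be read for the same reason. The rule for transcripts named in the text took, for each comparison, the largest rises and falls among calls with a mean of at least 1 CPM and no overlap between the 2 groups of 3 libraries; since identifiers had no names, at most 2 rises and 2 falls are printed, and their values were followed over all RNAi comparisons. The tests of the comparisons, the naming rule and these lists were chosen before the data were examined; tests and classes chosen later are named as such where their values stand.

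Lists defined from the data themselves were tested with fry (limma 3.58.1) on voom values, in libraries other than those that defined them. The wound lists hold transcripts that rose or fell at least 2-fold at adjusted p under 0.05 in the controls of the other experiment at the same time. The 0 hpa lists hold transcripts called in RNAi against control at 0 hpa, tested at later times and in the other experiment. Adjusted p-values of lists are Benjamini-Hochberg over the lists and comparisons of each family. fry asks whether the members of a list move, on balance, in 1 direction and does not compare the list with other transcripts. The competitive test camera was run with a preset correlation of 0.01 and with an estimated correlation. Counts of members that passed are given over all transcripts and adjusted over the list alone. A wound score per library was the mean log2 CPM (prior count 2) of the 48 hpa risen list minus that of the fallen list, divided by 2, less its mean in the 0 hpa controls. Scores were compared with an exact permutation test, two-sided. Overlaps were tested with Fisher's exact test, one-sided.

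The tests were checked on simulated data with the same libraries, depths and dispersions, in which known transcripts were changed in the RNAi group at 48 hpa. The changed transcripts were drawn from those with a mean of at least 1 CPM. All other groups shared the same mean per transcript, with no wound response and no difference between sets of libraries. The shares and false calls below need therefore not hold in the real fits. For myoD against control, 76.1% of transcripts changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold were called, with 8 false calls among 208. For fst against control the same shares were 47.8%, 77.6% and 93.9%, with 4 false calls among 151. For the difference between the effects they were 25.4%, 58.2% and 92.4%, with 2 false calls among 120. Of the 1128 pairs of libraries, none held copies of the same counts (lowest chi-squared per degree of freedom between the counts of a pair, 3.55).

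The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of only the groups compared, the replicate number as a block, each library left out in turn, other list rules and sizes, and both forms of camera. The library fst 48 hpa replicate 1 is marked in the labels for high human contamination. It was kept, and every count of the 6-feeding experiment was also computed without it. All columns of the count table were used (columns not used: 0).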

Results

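Amputation of a planarian tail fragment starts a wound response and the regrowth of a head, and the series asks how wound faces respond when myoD or follistatin is inhibited. myoD encodes a transcription factor of muscle, and follistatin (fst) encodes a secreted inhibitor of Activin-type signals. Wound faces were collected at 0, 6, 24 and 48 hours after amputation (hpa). In the experiment with 10 feedings of double-stranded RNA, the groups were control and myoD RNAi. In the experiment with 6 feedings, the groups were control and fst RNAi. Each of the 16 groups held 3 libraries. Total counts ran from 11698530 to 21974437 per library in the 10-feeding experiment. In the 6-feeding experiment they ran from 10209839 to 22065480 at 0 and 6 hpa and from 9265914 to 18733006 at 24 hpa. The shallowest groups were control at 48 hpa of the 6-feeding experiment (7169717 to 10545948) and fst at 48 hpa (7980762 to 9849182). Transcripts are given by identifier, since the files do not pair identifiers with gene names. The level of the targeted genes could not be read.

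In the controls of the 10-feeding experiment, dd_Smed_v4_16222_0_1 had the largest rise at 6 hpa, from 0.36 ± 0.186 to 15.8 ± 2.43 CPM (SD, n = 3), a log2 fold change of 5.44 (SE 0.32, adjusted p = 6.28e-12). It stayed at 11.9 ± 3.4 CPM at 24 hpa. dd_Smed_v4_1162_0_1 had the largest fall at 6 hpa, from 16.5 ± 0.797 to 4.32 ± 0.638 CPM. At 48 hpa, dd_Smed_v4_10584_0_1 rose from 0.207 ± 0.311 to 14.2 ± 2.76 CPM and dd_Smed_v4_8340_0_1 rose from 0.398 ± 0.18 to 11 ± 3.52 CPM. The largest fall at 24 hpa was that of dd_Smed_v4_1501_0_1, which had 351 counts at 0 hpa and 0 at 24 hpa, at least 127-fold lower. It varied between 0 hpa libraries (7.1 ± 4.87 CPM), and its adjusted p was 0.103 when only these groups were fitted. dd_Smed_v4_534_0_1 went from 708 counts at 0 hpa to 1 at 48 hpa, a ratio of 703 with a counting interval of 126 to 27800, and varied between 0 hpa libraries (14.4 ± 8.47 CPM). Over all transcripts tested, 1738 were higher and 1748 lower at 6 hpa than at 0 hpa, 2509 higher and 2884 lower at 24 hpa, and 3572 higher and 4076 lower at 48 hpa. The balance depended on the scaling: with RLE size factors 1835 were higher and 1610 lower at 6 hpa, 2718 and 2655 at 24 hpa, and 3830 and 3755 at 48 hpa, and DESeq2 also had more higher than lower at each time. Those changed at least 2-fold numbered 274 higher and 67 lower at 6 hpa and 407 higher and 621 lower at 48 hpa.

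In the controls of the 6-feeding experiment, dd_Smed_v4_16222_0_1 again had the largest rise at 6 hpa, from 0.225 ± 0.117 to 17.9 ± 2.41 CPM (SD, n = 3; log2 fold change 6.35, SE 0.29, adjusted p = 2.91e-13). dd_Smed_v4_9273_0_1 rose from 6.35 ± 1.56 to 66 ± 19 CPM at 6 hpa. dd_Smed_v4_14711_0_1 fell from 6.68 ± 1.09 CPM to 0.894 ± 0.407 at 6 hpa and 0.485 ± 0.23 at 24 hpa. dd_Smed_v4_12410_0_1 fell from 5.72 ± 0.344 to 0.339 ± 0.0922 CPM at 24 hpa. At 48 hpa, dd_Smed_v4_10584_0_1 reached 12.7 ± 0.669 CPM from a single count at 0 hpa, a ratio of 667 with a counting interval of 119 to 26400. At that time dd_Smed_v4_1501_0_1 was at 0 counts against 1780 at 0 hpa (32.3 ± 13.8 CPM), at least 340-fold lower, with an adjusted p of 0.0604 and 0.0586 without 48 hpa replicate 1 or 2. dd_Smed_v4_28185_0_1, also among the largest rises at 48 hpa, belongs to a small set of transcripts that separate whole groups of libraries, described with the fst comparison at 24 hpa. The 48 hpa and 0 hpa libraries lie on different sides of this split of the libraries, so the whole comparison of these times crosses it. Over all transcripts, 674 were higher and 500 lower at 6 hpa, 1524 higher and 1235 lower at 24 hpa, and 2846 higher and 2818 lower at 48 hpa (2775 and 2897 with RLE size factors). The 6 hpa total of 1174 was 398 without control 6 hpa replicate 3, 511 without 0 hpa replicate 2 and 546 without 0 hpa replicate 3. The 24 hpa total of 2759 was 1600 without 24 hpa replicate 1 and 1676 without 0 hpa replicate 2. When only the compared groups were fitted these totals were 726 and 5011, and without fst 48 hpa replicate 1, which enters the shared spread, the 6 hpa total was 2132.

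The wound responses of the controls of the 2 experiments shared more calls than chance at each time (Fisher's exact test, one-sided, unadjusted p of at most 1.94e-36). At 48 hpa, 2129 transcripts were higher and 2107 lower in both, against 575 and 657 by chance, and 13 and 30 went in opposite directions. At 6 hpa, 403 were higher and 149 lower in both, against 66.1 and 49.8 by chance, but 76 transcripts higher in the 10-feeding controls were lower in the 6-feeding controls. Across the 17288 transcripts tested in both, the log2 fold changes had a Pearson r of 0.16 at 6 hpa, 0.64 at 24 hpa and 0.78 at 48 hpa. Transcripts are not independent replicates.

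The comparison of myoD RNAi with control at 0 hpa asks what differed at the time of amputation. dd_Smed_v4_12634_0_1 was 17.4-fold lower after myoD RNAi, at 0.829 ± 0.199 against 14.4 ± 2.88 CPM in controls (SD, n = 3; log2 fold change -4.12, SE 0.30, adjusted p = 5.16e-08). dd_Smed_v4_18181_0_1 was 5.18-fold lower, at 1.05 ± 0.183 against 5.54 ± 0.728 CPM. dd_Smed_v4_1491_0_1 was 2.04-fold higher, at 218 ± 12.2 against 107 ± 8.36 CPM, and dd_Smed_v4_7888_0_1 was 1.96-fold higher. Both of these rises lost the call when single libraries were left out: the adjusted p of dd_Smed_v4_1491_0_1 was 0.0677 without control replicate 2 or 3 and 0.0629 without myoD replicate 1, and that of dd_Smed_v4_7888_0_1 was 0.122 and 0.159 without control replicate 1 or 2, 0.0757 and 0.138 without myoD replicate 1 or 3, and 0.169 when only these 6 libraries were fitted. All of these transcripts except dd_Smed_v4_7888_0_1 passed the test in the same direction at every later time. dd_Smed_v4_12634_0_1 had log2 fold changes of -3.22 at 6 hpa, -3 at 24 hpa and -4.16 at 48 hpa, and dd_Smed_v4_18181_0_1 had -1.82, -1.11 and -2.11. In fst RNAi against its own controls, dd_Smed_v4_12634_0_1 had log2 fold changes between -0.20 and 0.27 at the 4 times, with adjusted p of 0.422 or more. Without gene names, it could not be told whether this or another transcript lower at 0 hpa is the targeted one. In all, 8 transcripts were higher and 95 lower after myoD RNAi at 0 hpa, 10 of them at least 2-fold. The total of 103 was 48 without myoD replicate 1, 52 without myoD replicate 2, 50 without control replicate 3 and 67 without control replicate 2, and 197 when only these 6 libraries were fitted.

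At 6 hpa, the same dd_Smed_v4_12634_0_1 (9.32-fold lower, 0.92 ± 0.532 against 8.59 ± 1.87 CPM, SD, n = 3) and dd_Smed_v4_18181_0_1 (3.53-fold lower) had the largest falls after myoD RNAi. The largest rises were those of dd_Smed_v4_7888_0_1, 2.6-fold higher at 7.84 ± 0.865 against 2.97 ± 1.03 CPM, and dd_Smed_v4_8444_0_1, 1.83-fold higher at 38.2 ± 5.14 against 20.8 ± 1.89 CPM (adjusted p = 2.79e-05). dd_Smed_v4_16222_0_1, the transcript with the largest rise in controls, had a log2 fold change of -0.26 between myoD and control (SE 0.18, adjusted p = 0.637). Over all transcripts, 35 were higher and 64 lower. The total of 99 was 49, 40 and 41 without myoD replicate 1, 2 or 3, 34, 191 and 62 without control replicate 1, 2 or 3, and 155 with DESeq2.

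At 24 hpa, dd_Smed_v4_16222_0_1 was 12.6-fold lower after myoD RNAi, at 0.934 ± 0.374 against 11.9 ± 3.4 CPM (SD, n = 3; log2 fold change -3.65, SE 0.27, adjusted p = 9.08e-09). dd_Smed_v4_12634_0_1 was 8.01-fold lower. dd_Smed_v4_12035_0_1 was 4.54-fold higher, at 2.12 ± 0.336 against 0.479 ± 0.175 CPM, and dd_Smed_v4_16227_0_1 was 3.86-fold higher, at 8.27 ± 1.72 against 2.21 ± 0.478 CPM. In all, 434 transcripts were higher and 590 lower, 22 and 53 of them at least 2-fold. The total of 1024 was 356 without myoD replicate 2, 430 without control replicate 1, 460 without control replicate 3 and 532 when only these 6 libraries were fitted.

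At 48 hpa, myoD RNAi and control differed in 4488 transcripts, 2223 higher and 2265 lower, with 189 and 208 at least 2-fold. dd_Smed_v4_10584_0_1, which rose in controls, was 19-fold lower after myoD RNAi, at 0.729 ± 0.319 against 14.2 ± 2.76 CPM (SD, n = 3; log2 fold change -4.25, SE 0.44, adjusted p = 5.44e-06). dd_Smed_v4_16222_0_1 was 18.6-fold lower, at 0.341 ± 0.183 against 6.87 ± 1.4 CPM. dd_Smed_v4_12035_0_1 was 24-fold higher, at 5.32 ± 1.41 against 0.208 ± 0.149 CPM, and dd_Smed_v4_4427_0_1 was 10.4-fold higher, at 37.9 ± 3.02 against 3.62 ± 1.06 CPM (adjusted p = 8.68e-19). The total was 2730 without control replicate 1. The median of the absolute log2 fold changes among the calls was 0.40.

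**Figure D1:**
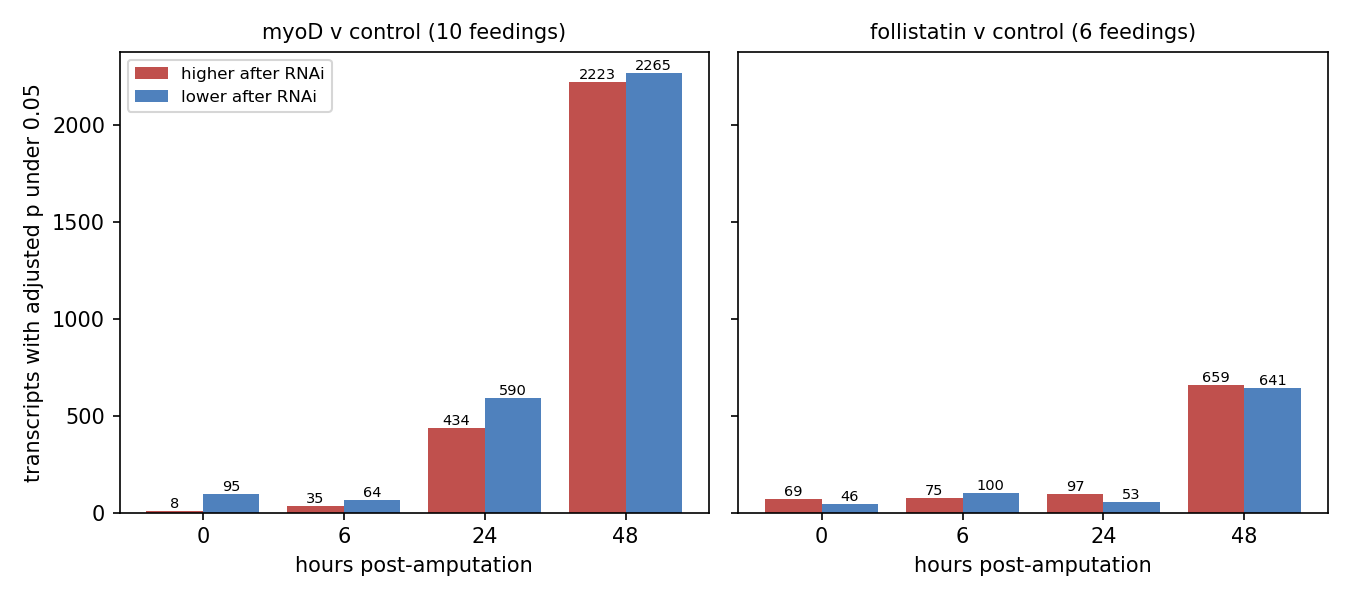
Transcripts called higher or lower in RNAi against control at each time after amputation, for myoD and for fst (vertical axis, number of transcripts at adjusted p under 0.05; horizontal axis, hours after amputation). At 48 hpa the numbers were 2223 higher and 2265 lower for myoD and 659 higher and 641 lower for fst.

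The wound lists ask whether transcripts that respond to amputation did so to a lesser extent after RNAi, with lists taken from the controls of the other experiment. The 48 hpa lists and the wound score used for myoD come from the 6-feeding controls, whose comparison of 48 with 0 hpa crosses the split of the libraries. Members of the risen and fallen list also changed in the 10-feeding controls by then, by medians of 0.97 and -1.19. At 48 hpa, 317 of 527 transcripts of the risen list were lower after myoD RNAi and 5 higher (346 lower and 7 higher adjusted over the list alone). Their median log2 fold change was -0.71 (adjusted p = 1.07e-09). Of 530 transcripts of the fallen list, 249 were higher and 0 lower (280 and 0 adjusted over the list alone), with a median of 0.63 (adjusted p = 7.26e-06). At 24 hpa, 77 of 233 transcripts of the risen list were lower and 3 higher (106 and 7 adjusted over the list alone), with a median of -0.44 (adjusted p = 7.26e-06). The fallen list at 24 hpa had a median of 0.10, with 14 of 168 higher and 1 lower (15 and 2 adjusted over the list alone); its adjusted p of 0.0298 became an adjusted p = 0.159 with an estimated correlation. At 6 hpa, the risen list had a median of -0.10 (adjusted p = 0.106), with 3 of 96 lower and 0 higher (5 and 0 adjusted over the list alone). The fallen list at 6 hpa had a median of 0.10 and 0 of 129 members passed in edgeR or in DESeq2, also when adjusted over the list alone (8 higher and 5 lower at an unadjusted p under 0.05 in edgeR, 5 and 2 in DESeq2); its adjusted p of 0.0456 became an adjusted p = 0.159 with an estimated correlation. Its members did not fall in the 10-feeding controls, where they changed by a median of 0.28 from 0 hpa, so the shift is not a smaller fall. The calls for the risen lists at 24 and 48 hpa and the fallen list at 48 hpa held with an estimated correlation (adjusted p = 0.0046, 0.000364 and 0.0166).

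After myoD RNAi, dd_Smed_v4_16222_0_1 rose at 6 hpa from 0.227 ± 0.0733 to 13.3 ± 1.91 CPM (SD, n = 3; log2 fold change 5.84, SE 0.34, adjusted p = 5.42e-12). dd_Smed_v4_238_0_1 went from 1 count at 0 hpa to 174 at 6 hpa, a ratio of 184 with a counting interval of 32.6 to 7310. At 24 hpa, dd_Smed_v4_12565_0_1 rose from 0.329 ± 0.128 to 4.31 ± 1.17 CPM. At 48 hpa, dd_Smed_v4_4939_0_1 rose from 3.5 ± 1.76 to 27.1 ± 11.3 CPM, while dd_Smed_v4_41_1_1 had 0 counts against 433 at 0 hpa, at least 126-fold lower (adjusted p 0.0862 and 0.0569 without 48 hpa replicate 1 or 2, edgeR). Against 0 hpa, 1726 transcripts were higher and 1248 lower at 6 hpa, 1623 higher and 1538 lower at 24 hpa, and 736 higher and 1070 lower at 48 hpa. The 48 hpa total of 1806 was 888 without myoD 48 hpa replicate 1 and 1117 without 0 hpa replicate 2, and the 6 hpa total of 2974 was 1963 without 0 hpa replicate 1.

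The myoD effect differed between times in 1962 transcripts by the test of the interaction (1181 without control 48 hpa replicate 1). For the members of the risen wound list at 48 hpa, the median log2 change from 0 hpa was 0.97 in controls and 0.29 after myoD RNAi, and 83.7% of the 527 members had the smaller change after RNAi. The fallen list changed by a median of -1.19 in controls and -0.54 after myoD RNAi. The test of these changes between controls and RNAi was chosen after the data were seen. Both differences passed the test (adjusted p = 9.24e-07 and 0.000256; 0.00156 and 0.0253 with an estimated correlation). The wound score per library was 1.28 ± 0.151 in controls and 0.569 ± 0.0292 after myoD RNAi at 48 hpa, and 0.82 ± 0.0796 and 0.608 ± 0.121 at 24 hpa (SD, n = 3). At both times all control libraries lay above all myoD libraries, with an exact permutation p of 0.1, the smallest that 3 against 3 allows. At 6 hpa the scores were 0.379 ± 0.124 and 0.233 ± 0.0444 (exact permutation p = 0.2).

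**Figure D2:**
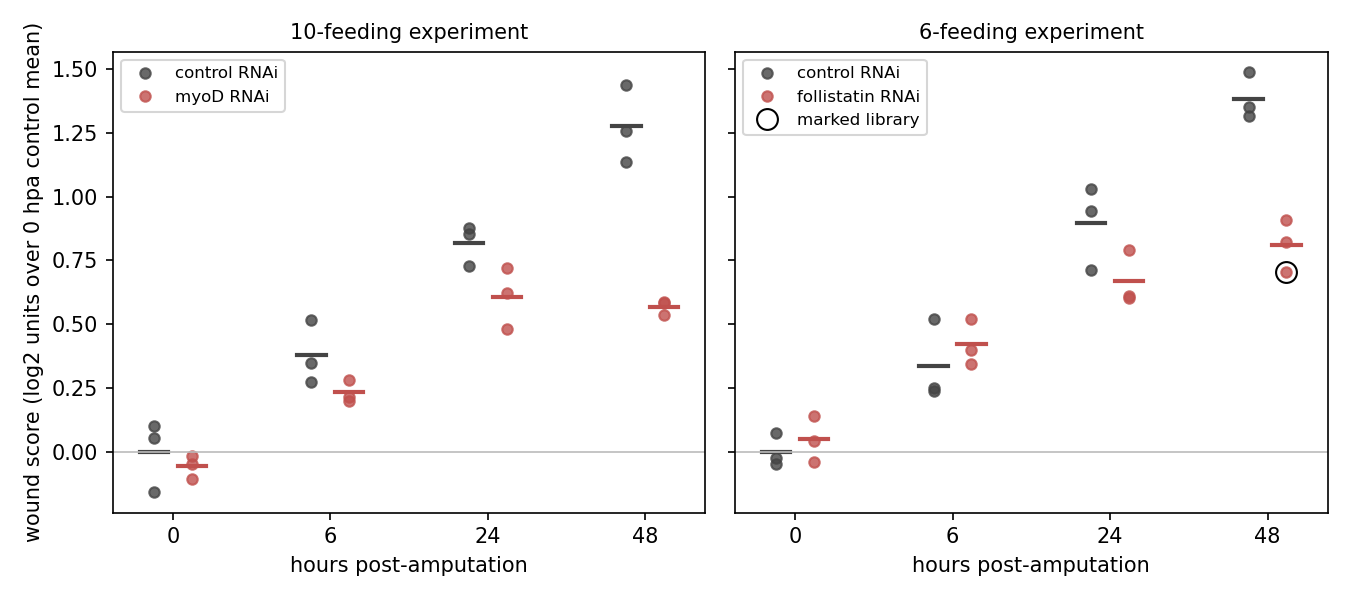
Wound score of each library (vertical axis, log2, relative to the 0 hpa controls of the same experiment) against hours after amputation, with 1 point per library and lines through group means of 3 libraries. At 48 hpa the control means were 1.28 and 1.38, against 0.569 for myoD and 0.812 for fst.

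The transcripts that differed at 0 hpa were followed to later times. Of the 95 transcripts lower after myoD RNAi at 0 hpa, 37 were lower and 0 higher at 6 hpa (83 and 0 adjusted over the list alone), with a median log2 fold change of -0.30 (adjusted p = 2.39e-06, and 0.000245 with an estimated correlation). At 24 hpa, 25 were lower and 3 higher (39 and 6 adjusted over the list alone), and at 48 hpa 35 were lower and 8 higher (36 and 9 adjusted over the list alone). The medians of -0.15 and -0.12 had adjusted p-values of 0.0016 and 0.000353; with an estimated correlation the adjusted p = 0.0681 at 24 hpa and 0.15 at 48 hpa. In fst RNAi at 48 hpa, 21 of these 95 transcripts were higher and 9 lower (30 and 11 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.000411, and 0.0296 with an estimated correlation). That median was -0.19 when only transcripts lower at least 2-fold at 0 hpa were kept. In fst RNAi at 0, 6 and 24 hpa, the medians were -0.13 (adjusted p = 0.000139, and 0.000788 with an estimated correlation, a call lost with the 2-fold members alone), -0.07 (adjusted p = 0.0914) and -0.04 (adjusted p = 0.725). Of the 8 transcripts higher after myoD RNAi at 0 hpa, 6 were higher at 6 hpa, 5 at 24 hpa and 7 at 48 hpa, where 1 was lower.

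At 0 hpa, dd_Smed_v4_42763_0_1 was 8.75-fold higher after fst RNAi, at 5.74 ± 0.665 against 0.673 ± 0.198 CPM in controls (SD, n = 3; log2 fold change 3.13, SE 0.41, adjusted p = 0.000493). dd_Smed_v4_22973_0_1 was 3.4-fold higher, at 3.96 ± 1.3 against 1.22 ± 0.649 CPM. dd_Smed_v4_10973_0_1 was 2.37-fold lower, at 2.13 ± 0.442 against 5.06 ± 0.642 CPM (adjusted p = 0.0496), and dd_Smed_v4_1616_0_1 was 2.31-fold lower. The call for dd_Smed_v4_10973_0_1 was lost without any 1 of control replicates 1, 2 and 3 (adjusted p 0.133, 0.241 and 0.115) or fst replicates 1, 2 and 3 (0.168, 0.102 and 0.302) and with the replicate block (0.0555). That for dd_Smed_v4_1616_0_1 was lost without control replicate 1 or 2 (0.101 and 0.0743) or fst replicate 1, 2 or 3 (0.0929, 0.0591 and 0.101), and that for dd_Smed_v4_22973_0_1 without control replicate 1 or 2 (0.0572 and 0.0769) or fst replicate 3 (0.0767). dd_Smed_v4_42763_0_1 remained higher at 6, 24 and 48 hpa, with log2 fold changes of 2.78, 1.8 and 2.09. In all, 69 transcripts were higher and 46 lower at 0 hpa. The total of 115 was 24, 17 and 52 without control replicate 1, 2 or 3, 54, 32 and 23 without fst replicate 1, 2 or 3, and 263 with DESeq2. It was 990 when only these 6 libraries were fitted and 322 without fst 48 hpa replicate 1, the library marked for human contamination, which enters the shared spread.

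At 6 hpa, dd_Smed_v4_315_0_1 was 3.33-fold lower after fst RNAi, at 68.8 ± 13.9 against 229 ± 51.1 CPM (SD, n = 3; log2 fold change -1.74, SE 0.21, adjusted p = 0.000315). dd_Smed_v4_8029_0_1 was 3.24-fold lower, at 8.71 ± 0.477 against 28.3 ± 3.9 CPM. dd_Smed_v4_42763_0_1 was 6.87-fold higher, and dd_Smed_v4_28487_0_1 was 3.16-fold higher, at 1.73 ± 0.301 against 0.506 ± 0.271 CPM. The adjusted p of dd_Smed_v4_28487_0_1 was 0.0547 and 0.0876 without control replicate 1 or 2, 0.0626 and 0.0916 without fst replicate 2 or 3, and 0.0555 when only these groups were fitted, and DESeq2 gave it none. Over all transcripts, 75 were higher and 100 lower. The total of 175 was 91 and 97 without control replicate 2 or 3, and 60, 51 and 72 without fst replicate 1, 2 or 3. It was 460 with DESeq2 and 571 without fst 48 hpa replicate 1.

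At 24 hpa, dd_Smed_v4_16222_0_1 was 4.66-fold lower after fst RNAi, at 3.18 ± 0.721 against 14.9 ± 1.86 CPM (SD, n = 3; log2 fold change -2.22, SE 0.20, adjusted p = 1.47e-07), and dd_Smed_v4_22061_0_1 was 4.99-fold lower, at 1.08 ± 0.238 against 5.63 ± 1.8 CPM. The latter had an adjusted p of 0.0669 without control replicate 2, and of 0.056 and 0.0815 without fst replicate 2 or 3. The largest rises were those of dd_Smed_v4_28185_0_1, with 194 counts against 0 (at least 80.4-fold higher), and dd_Smed_v4_95764_0_1, with 84 counts against 1 (a ratio of 104 with a counting interval of 18.2 to 4170). These 2 transcripts, with dd_Smed_v4_18014_0_1 and dd_Smed_v4_7642_0_1, which were chosen after their values were seen, were raised in all 9 libraries of fst 24 hpa, control 48 hpa and fst 48 hpa and at least 4-fold lower in each of the other 15 libraries of this experiment. Of the 56 ways to part its groups 3 against 5, this was the only one with such transcripts (highest of the others, 0). The comparison at 24 hpa crosses this split, and the split and the fst effect at 24 hpa cannot be told apart. In all, 97 transcripts were higher and 53 lower, and 135 of the 150 remained when those called in the same direction in the difference between the control responses at 48 hpa were left out. Among the 150, however, the log2 fold changes had a Pearson r of 0.81 with that difference, across transcripts, against 0.38 among the calls at 6 hpa and 0.54 among those at 0 hpa, which share the 0 hpa controls with it. The total was 83 and 76 without control replicate 1 or 2, 77 and 83 without fst replicate 2 or 3, 239 with DESeq2, 321 when only these 6 libraries were fitted and 381 without fst 48 hpa replicate 1.

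**Figure D3:**
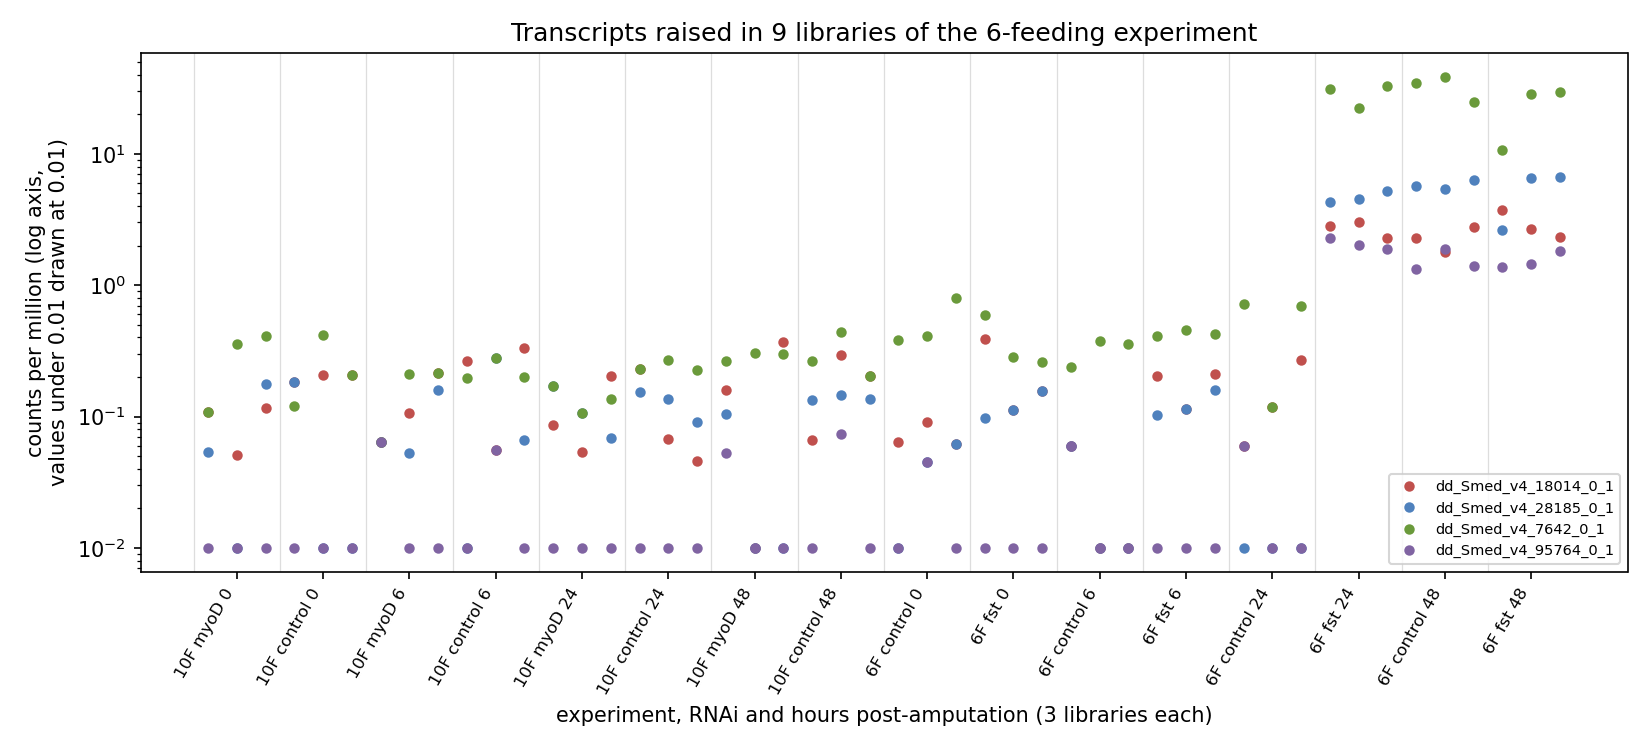
Levels of dd_Smed_v4_18014_0_1, dd_Smed_v4_28185_0_1, dd_Smed_v4_7642_0_1 and dd_Smed_v4_95764_0_1 in every library (vertical axis, CPM of the library total on a log scale; horizontal axis, libraries by group). In the 9 libraries, dd_Smed_v4_7642_0_1 lay between 10.7 and 38.7 CPM, against at most 0.804 in the other 15 of the 6-feeding experiment.

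At 48 hpa, fst RNAi and control, which lie on the same side of that split, differed in 1300 transcripts, 659 higher and 641 lower, with 143 and 82 at least 2-fold. dd_Smed_v4_12035_0_1 was 15.2-fold higher, at 3.65 ± 1.06 against 0.204 ± 0.21 CPM (SD, n = 3; log2 fold change 3.93, SE 0.40, adjusted p = 3.9e-07), and dd_Smed_v4_16227_0_1 was 13.3-fold higher, at 10.2 ± 5.32 against 0.79 ± 0.568 CPM. dd_Smed_v4_22630_0_1 was 13.7-fold lower, at 0.175 ± 0.0332 against 2.54 ± 0.493 CPM, and dd_Smed_v4_44405_0_1 was 10.4-fold lower; DESeq2 gave neither of these falls an adjusted p. In the marked library fst 48 hpa replicate 1, 37 transcripts were at least 4-fold above every other library of the experiment and took 12.2% of its counts, against at most 1.95% in any of the other libraries of the experiment. Without that library 1214 transcripts were called, of which 818 were among the 1300. The total was 722 and 671 without control replicate 1 or 2 and 127 when only these 6 libraries were fitted.

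In the wound lists, 146 of 398 transcripts of the risen list were lower after fst RNAi at 48 hpa and 2 higher (187 and 2 adjusted over the list alone), with a median log2 fold change of -0.61 (adjusted p = 5.06e-09, and 5.15e-05 with an estimated correlation). Of 599 transcripts of the fallen list, 110 were higher and 4 lower (145 and 5 adjusted over the list alone), with a median of 0.48 (adjusted p = 0.000502, and 0.0181 with an estimated correlation). At 24 hpa, where the comparison crosses the split of the libraries, the risen list had a median of -0.07 (adjusted p = 0.0894). Of its 272 members, 10 were lower and 2 higher (30 and 4 adjusted over the list alone). The fallen list at 24 hpa had a median of 0.34, with 17 of 284 higher and 1 lower (30 and 2 adjusted over the list alone); its adjusted p of 0.0456 became an adjusted p = 0.102 with an estimated correlation, and the median was -0.00193 for the list without a fold minimum. At 6 hpa the risen list was higher, with a median of 0.27, and 6 of 238 passed (12 higher and 2 lower adjusted over the list alone); its adjusted p of 0.0166 became an adjusted p = 0.101 with an estimated correlation, and its members changed from 0 hpa by a median of 0.11 in the 6-feeding controls. The fallen list at 6 hpa had a median of 0.02 and a test direction of lower (adjusted p = 0.85), with 1 of 67 higher and 1 lower, also when adjusted over the list alone.

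Of the 69 transcripts higher after fst RNAi at 0 hpa, 29 were higher at 6 hpa, 19 at 24 hpa and 48 at 48 hpa (56, 38 and 54 adjusted over the list alone). The median log2 fold changes were 0.39, 0.27 and 0.58, and the largest of the adjusted p-values was 4.48e-06 (0.000431 with an estimated correlation). Of these 69 transcripts, 44 were also higher and 8 lower in myoD RNAi at 48 hpa (46 and 11 adjusted over the list alone), with a median of 0.37 (adjusted p = 4.6e-06, and 0.0402 with an estimated correlation). Earlier in myoD RNAi, their median was -0.07 at 0 hpa (adjusted p = 0.18; 2 higher and 0 lower, 2 and 5 adjusted over the list alone), 0.11 at 6 hpa (adjusted p = 0.0197, and adjusted p = 0.0876 with an estimated correlation; 2 and 0, 7 and 2 adjusted over the list alone) and 0.22 at 24 hpa (adjusted p = 0.000534, and 0.0402 with an estimated correlation; 24 and 5, 32 and 7 adjusted over the list alone). The calls at 6 and 24 hpa were lost when only members changed at least 2-fold were kept. Of the 46 transcripts lower after fst RNAi at 0 hpa, 23 were lower at 6 hpa (median -0.60, adjusted p = 1.16e-06), 7 at 24 hpa (median -0.18, adjusted p = 0.0077, with an estimated correlation adjusted p = 0.0618) and 13 at 48 hpa (median -0.34, adjusted p = 0.000402). Adjusted over the list alone, these were 40, 7 and 25. The fst comparison at 24 hpa crosses the split of the libraries. In myoD RNAi, these 46 transcripts had medians between -0.03 and 0.08 at the 4 times, with adjusted p of 0.169 or more.

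Within the fst RNAi animals, dd_Smed_v4_16222_0_1 rose at 6 hpa from 0.289 ± 0.124 to 20.2 ± 3.92 CPM (SD, n = 3; log2 fold change 6.01, SE 0.28, adjusted p = 4.18e-13), and dd_Smed_v4_28398_0_1 rose from 0.361 ± 0.248 to 6.09 ± 1.5 CPM. dd_Smed_v4_14711_0_1 fell from 9.12 ± 1.47 CPM to 0.978 ± 0.301 at 6 hpa and 0.39 ± 0.226 at 24 hpa. At 48 hpa, dd_Smed_v4_735_0_1 had 0 counts against 1295 at 0 hpa, at least 264-fold lower, and dd_Smed_v4_1577_0_1 had 0 against 1029. Both varied between 0 hpa libraries (29.4 ± 21.5 and 23.1 ± 17 CPM), and 1 library held 829 and 671 of these counts. Their adjusted p-values were 0.06 and 0.0619 without fst 48 hpa replicate 1, 0.0502 and 0.054 without 0 hpa replicate 3, and 0.0624 and 0.0659 when only these groups were fitted. Against 0 hpa, 869 transcripts were higher and 507 lower at 6 hpa, 779 higher and 906 lower at 24 hpa, and 1883 higher and 1741 lower at 48 hpa. The comparisons at 24 and 48 hpa cross the split of the libraries. Without fst 48 hpa replicate 1 the totals of 1376, 1685 and 3624 were 2329, 2891 and 2016. The balance at 48 hpa then turned, with 893 higher and 1123 lower. It also turned with no filter on low counts (1424 and 1699) and when only these groups were fitted (179 and 405). With RLE size factors, the replicate block and DESeq2 it did not turn. The 48 hpa total was also 2213 and 2269 without 0 hpa replicate 1 or 2, the 24 hpa total 934, 1070 and 957 without 0 hpa replicate 1, 2 or 3 and 694 without 24 hpa replicate 3, and the 6 hpa total 797 and 795 without 0 hpa replicate 1 or 2 and 904 and 682 without 6 hpa replicate 2 or 3.

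The fst effect differed between times in 369 transcripts by the test of the interaction. It was 223 and 192 without control 48 hpa replicate 1 or 2, 744 without fst 48 hpa replicate 1, and 738 with DESeq2. The 24 hpa term of this test crosses the split of the libraries. With only the 6 and 48 hpa terms, and in a fit without the 24 hpa groups, the number stayed within 1.5 times the reported one. Both of these were chosen after the data were seen. For the risen wound list at 48 hpa, the median log2 change from 0 hpa was 1.21 in controls and 0.57 after fst RNAi, with the smaller change after RNAi in 86.2% of 398 members (adjusted p = 2.51e-07). The fallen list changed by a median of -1.15 and -0.60 (adjusted p = 0.00533). These tests of the change were chosen after the data were seen. Each change from 0 to 48 hpa crosses the split of the libraries, while the 2 groups at 48 hpa lie on the same side of it. The wound score at 48 hpa was 1.38 ± 0.0907 in controls and 0.812 ± 0.104 after fst RNAi (SD, n = 3), with all control libraries above all fst libraries (exact permutation p = 0.1, the smallest that 3 against 3 allows). The mean was 0.866 without fst replicate 1. The comparison of scores at 24 hpa crosses the split of the libraries. At 24 hpa the scores were 0.896 ± 0.164 in controls and 0.669 ± 0.107 after fst RNAi (SD, n = 3; exact permutation p = 0.2), and at 6 hpa 0.337 ± 0.16 and 0.423 ± 0.0905 (exact permutation p = 0.5).

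The effects of myoD and fst RNAi, measured against separate controls, shared more called transcripts at 48 hpa than at the earlier times. More transcripts were also called in each experiment at 48 hpa. dd_Smed_v4_12035_0_1, dd_Smed_v4_16227_0_1 and dd_Smed_v4_4427_0_1 were higher and dd_Smed_v4_16222_0_1, dd_Smed_v4_10584_0_1, dd_Smed_v4_22630_0_1 and dd_Smed_v4_44405_0_1 lower in both. dd_Smed_v4_4427_0_1 had log2 fold changes of 3.39 (SE 0.13) in myoD and 3.71 (SE 0.18) in fst, and dd_Smed_v4_22630_0_1 had -3.26 (SE 0.52) and -3.77 (SE 0.45). In all, 447 transcripts were higher and 502 lower in both, against 84.1 and 83.3 by chance, and 2 and 4 went in opposite directions (Fisher's exact test, adjusted p = 1.32e-250 for the transcripts higher in both). At 24 hpa, 29 were higher and 7 lower in both, against 2.05 and 1.81 by chance (adjusted p = 1.43e-25 and 0.00325). The fst comparison at that time crosses the split of the libraries. At 0 hpa, 2 were higher in both (0.0319 by chance, adjusted p = 0.000866) and 1 lower (adjusted p = 0.256). At 6 hpa, 1 was higher (adjusted p = 0.188) and 0 lower (adjusted p = 1). The odds ratios at 0, 6, 24 and 48 hpa were 85.5, 6.82, 22.7 and 18 for transcripts higher in both. For those lower in both they were 4.05, 0, 4.35 and 31.4. Those at 0 and 6 hpa rest on at most 2 shared transcripts. Across 17288 transcripts, which are not independent replicates, the effects had a Pearson r of -0.09 at 0 hpa, -0.14 at 6 hpa, 0.16 at 24 hpa and 0.49 at 48 hpa.

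**Figure D4:**
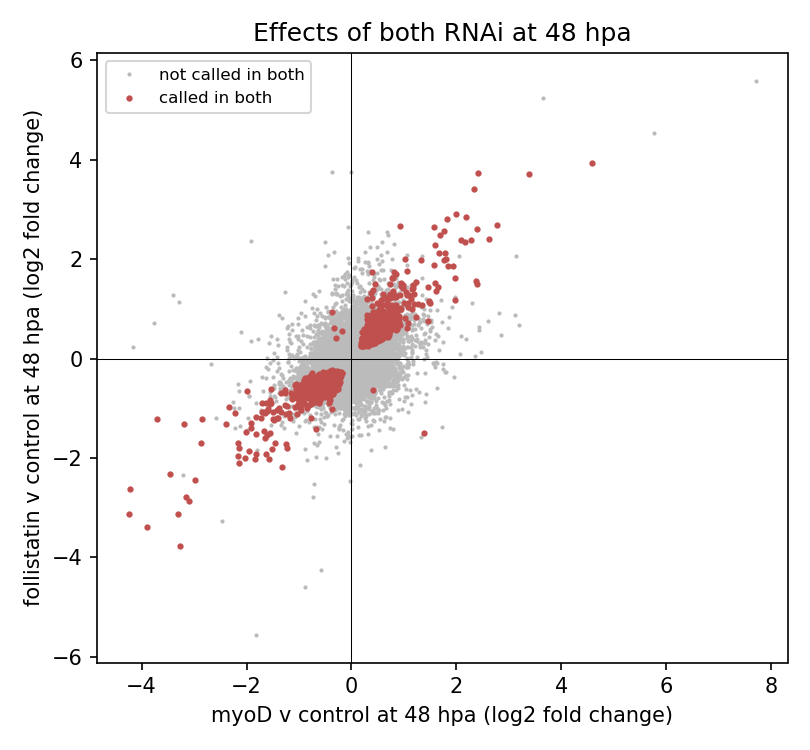
Log2 fold change at 48 hpa of fst RNAi (vertical axis) against that of myoD RNAi (horizontal axis), each against its own controls, with 1 point per transcript. Across the 17288 transcripts the Pearson r was 0.49, and 447 transcripts were higher and 502 lower in both.

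The difference between the myoD effect and the fst effect passed the test for 132 transcripts at 0 hpa, 312 at 6 hpa, 93 at 24 hpa and 95 at 48 hpa. At 48 hpa 30 were higher and 65 lower in myoD than in fst. These differences also contain that between 10 and 6 feedings, and the one at 24 hpa contains the split of the libraries that the fst comparison at 24 hpa crosses. At 6 hpa 183 were higher and 129 lower. The totals were 222, 561, 177 and 216 with DESeq2, and the 0 hpa total was 581 when only these groups were fitted. At 0 hpa the total was 49 and 79 without myoD replicate 1 or 2, 68 and 70 without 10-feeding control replicate 1 or 3, 75 and 72 without 6-feeding control replicate 1 or 2, and 70 and 61 without fst replicate 2 or 3. At 6 hpa it was 180, 194 and 131 without myoD replicate 1, 2 or 3, 193 and 114 without 10-feeding control replicate 1 or 2, 195 without 6-feeding control replicate 3 and 133 without fst replicate 2. At 24 hpa it was 60 without myoD replicate 2 and 59 without 10-feeding control replicate 3 or 6-feeding control replicate 1 or 2. Without fst 48 hpa replicate 1 the first 3 totals were 224, 700 and 187. At 48 hpa the total was 55, 42 and 63 without myoD replicate 1, 2 or 3, 59 and 50 without 6-feeding control replicate 1 or 2, 464 without fst replicate 3, 428 without fst replicate 2, 165, 58 and 41 without 10-feeding control replicate 3, 2 or 1, and 9 when only these groups were fitted.

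The authors' deposited tables held fewer transcripts at an adjusted p under 0.05 in each comparison than the edgeR fits called. For myoD against control at 0, 6, 24 and 48 hpa, the authors' deposited tables held 78, 45, 459 and 3049 such transcripts, and for fst against control 69, 104, 86 and 425. Of those in the authors' deposited table for 48 hpa, 3012 for myoD and 419 for fst were also called in the edgeR fit, all in the same direction; of those for fst against control in the authors' deposited tables, 51 of 69 were also called at 0 hpa and 79 of 104 at 6 hpa. For the changes from 0 to 6, 24 and 48 hpa, the authors' deposited tables held 2148, 3877 and 6203 transcripts for the 10-feeding controls and 1819, 2022 and 1083 for myoD. For the 6-feeding controls the authors' deposited tables held 481, 1250 and 3279 transcripts, and for fst 583, 570 and 1076. The log2 fold changes of the authors' deposited tables and of the edgeR fits had a correlation across transcripts between 0.992 and 1 over the 20 comparisons.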

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

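The counts of splits and the tests of scaling, of time, of human reads and library batch behind the split of the libraries, and of a reduced wound response in both RNAi experiments were chosen after the results were seen; those of depth, of a delay and of the marked library in the shared effects were chosen before.

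The effect of myoD RNAi differed between times in 1962 transcripts and that of fst RNAi in 369, by tests of the interaction. The effects of the 2 treatments differed from each other in 132 transcripts at 0 hpa, 312 at 6 hpa, 93 at 24 hpa and 95 at 48 hpa. The fst effect over time and the difference at 24 hpa contain the split of the libraries.

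The first pattern was the smaller wound response at 48 hpa after myoD RNAi. A shift of scaling between libraries would move risen and fallen wound transcripts the same way, and the fallen list had a median log2 fold change of 0.63 against -0.71 for the risen list, which argues against it. With every library thinned to 11698530 counts, 4115 transcripts were called, of which 3895 were among the 4488, which argues against a difference in depth. Had the whole response been late by 1 sampling step, myoD 48 hpa would differ little from control 24 hpa, but they differed in 3025 transcripts against 1024 between myoD and control at 24 hpa, which argues against such a delay as the whole cause. The myoD 48 hpa libraries differed from control 0, 6 and 48 hpa in 2691, 6234 and 4488 transcripts. Fewer calls thus separated them from control at 0 and 24 hpa than from control at 48 hpa, but a number of calls is not a distance. Across transcripts, their change from 0 hpa had a Pearson r of 0.594 with that of the 6-feeding controls at 48 hpa. It was 0.532 at 24 hpa and 0.207 at 6 hpa. The 10-feeding controls at 24 hpa also had a higher r with 48 hpa (0.659) than with 24 hpa (0.643), so these values do not place a time. A delay of part of the response, a different mix of cells in the wound, and an effect of myoD on the response itself stay open and were not tested.

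The second pattern was the set of 4 transcripts raised in all 9 libraries of fst 24 hpa, control 48 hpa and fst 48 hpa of the 6-feeding experiment. Time after amputation is argued against, since in the 10-feeding controls at 48 hpa they reached at most 12.8% of the 6-feeding control mean. Human reads of the marked library alone are argued against, since all 4 were raised in the other 8 libraries too. There dd_Smed_v4_18014_0_1, dd_Smed_v4_28185_0_1, dd_Smed_v4_7642_0_1 and dd_Smed_v4_95764_0_1 had at least 1.78, 4.32, 22.2 and 1.33 CPM. In the other 15 they had at most 0.392, 0.159, 0.804 and 0.0599. In the marked library, dd_Smed_v4_28185_0_1 and dd_Smed_v4_7642_0_1 were lower than in each of the 8 (0.472 and 0.352 of their mean). The level there does not decide for dd_Smed_v4_95764_0_1 (0.783, within their range) and dd_Smed_v4_18014_0_1 (1.5, above it). Human reads in the 8, which carry no such mark, were not tested. A library batch may have caused it, and stays open: the fst effect at 24 hpa had a correlation across transcripts of 0.29 with the difference between the 6-feeding and 10-feeding control responses at 48 hpa, against 0.13 at 6 hpa, but whole groups lie on either side, and the effect at 0 hpa, which crosses no split but shares the 6-feeding control libraries at 0 hpa with that difference, had 0.26. No biological explanation was tested.

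The third pattern was the similarity of the myoD and fst effects at 48 hpa. Human reads in the marked library are argued against as its source, since the correlation across transcripts was 0.509 without that library and 0.489 with it. A reduced wound response in both is a candidate explanation. With responders chosen in the 10-feeding controls alone, whose libraries enter only the myoD effect, the correlation was 0.25 among transcripts with no response and 0.65 among responders, and with the 6-feeding controls alone 0.3 and 0.67. Transcripts without a response also hold less signal, which may lower a correlation too.

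Other splits of the same libraries were fitted beside the real grouping. In the comparisons of 3 libraries against 3, every other split mixes the libraries of both groups. A real difference between the groups then enters the spread within them, which lowers the calls. The counts of these other splits are therefore not the number to be had by chance. For the 20 comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each only the real split, 1 of the 10, gave as many calls. For myoD against control at 0, 6, 24 and 48 hpa, the real numbers were 103, 99, 1024 and 4488, and the highest of the other splits 0, 1, 8 and 0. For fst against control they were 115, 175, 150 and 1300, and the highest others 0, 4, 0 and 82. For the 10-feeding controls the real numbers were 3486, 5393 and 7648, and for the 6-feeding controls 1174, 2759 and 5664, with 0 as the highest other in each. For myoD over time they were 2974, 3161 and 1806 (highest others 0, 0 and 2), and for fst 1376, 1685 and 3624 (highest other 0 in each).

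For the tests of differences between effects 25 splits were taken, the real one included. For the fst effect over time (369; highest other 60) and for the differences between the effects at 0 hpa (132; 44), 6 hpa (312; 114) and 24 hpa (93; 81), only 1 of the 25 gave as many calls, the smallest share these splits can give, with no correction over the 6 tests. Taken alone, this share is under 0.05. It would not stay under 0.05 with a correction over the 6 tests, so chance is not excluded by these counts. Splits that mix groups here also put real effects into the spread, which can lower their calls. The real grouping of the fst effect over time also holds the split of the libraries at 24 hpa. Its full count therefore cannot be attributed to RNAi alone. With only the 6 and 48 hpa terms, and in a fit without the 24 hpa groups, the number stayed within 1.5 times this count. Both of these fits were chosen after the data were seen. With single libraries left out, the lowest numbers were 192 for the fst effect over time and 49 for the difference at 0 hpa. In such fits, the numbers for the differences at 6 and 24 hpa fell to or under the highest other split. At 6 hpa the number was 114 without 10-feeding control replicate 2. At 24 hpa it was 60 without myoD replicate 2 and 59 without 10-feeding control replicate 3 or 6-feeding control replicate 1 or 2. For the myoD effect over time, 2 of the 25 splits gave as many calls (1962 against 2165), so chance cannot be excluded by this count. The other split kept the groups at 48 hpa whole, and so kept the RNAi effect at that time in the data. The highest of the splits that did not gave 0. For the difference between the effects at 48 hpa, 9 of the 25 gave as many calls (95 against 3727), so chance is not excluded by this count. These splits leave the RNAi effects in the data. In the real grouping, effects that myoD and fst share cancel, and a split that mixes or swaps the labels of an experiment undoes that. Such splits can call more transcripts than the real grouping, so this count is no measure of chance here. Of the splits with as many calls, 6 kept the 48 hpa groups of an experiment whole, and the highest of those that kept neither gave 764. How much of these counts comes from uncancelled effects was not tested.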

How the results depend on the processing

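The fits without fst 48 hpa replicate 1 for comparisons that do not hold it, those without 24 hpa or its groups, and that without transcripts following the control difference were chosen after seeing the data; all others were planned. Of 360 counts under alternatives, 247 lay within 1.5 times the reported one, 83 were lower and 30 higher; RLE size factors, no filter on low counts and the replicate block left 26 of 26 within 1.5 times each. The cause was not tested for any of the changes below. No pairing of the libraries by replicate number was detected: in 0 of 20 comparisons were all 3 correlations of same-number libraries over 0.1 (range -0.2 to 0.23).

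DESeq2 gave 155 for myoD at 6 hpa, 263, 460 and 239 for fst at 0, 6 and 24 hpa, 738 for the fst effect over time, and 222, 561, 177 and 216 for the myoD effect against the fst effect at 0, 6, 24 and 48 hpa. Fits of only the groups compared gave 197 and 532 for myoD at 0 and 24 hpa, 990, 321 and 127 for fst at 0, 24 and 48 hpa, 726 and 5011 for 6-feeding controls at 6 and 24 hpa against 0 hpa, 2847, 2768 and 584 for fst at 6, 24 and 48 hpa against 0 hpa, and 581 and 9 for the difference between effects at 0 and 48 hpa.

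Leaving out 1 library gave ranges of 48 to 90, 34 to 191, 356 to 1258 and 2730 to 4465 for myoD v control at 0, 6, 24 and 48 hpa, 17 to 322, 51 to 571, 76 to 381 and 671 to 1908 for fst v control at those times. For fst at 0, 6 and 24 hpa, the upper ends come from leaving out fst 48 hpa replicate 1, which lies outside the compared groups. With only libraries of the compared groups left out, these ranges were 17 to 54, 51 to 118 and 76 to 127. The ranges were 2379 to 3155, 4042 to 4895 and 6070 to 7182 for 10-feeding controls at 6, 24 and 48 hpa against 0 hpa, 1963 to 2390, 2115 to 3132 and 888 to 1758 for myoD likewise, 398 to 2132, 1600 to 4018 and 4481 to 6886 for 6-feeding controls likewise, 682 to 2329, 694 to 2891 and 2016 to 4439 for fst likewise. The ranges were 1181 to 2646 and 192 to 744 for the myoD and fst effects over time, 49 to 224, 114 to 700, 59 to 187 and 41 to 464 for the differences between effects at 0, 6, 24 and 48 hpa. Some further upper ends also come from leaving out fst 48 hpa replicate 1 from outside the groups. Without that fit, the 6-feeding controls had 398 to 1307, 1600 to 2171 and 4481 to 4956. For fst at 6 and 24 hpa against 0 hpa, the ranges were then 682 to 1217 and 694 to 1564. For the differences at 0, 6 and 24 hpa they were 49 to 113, 114 to 446 and 59 to 118.

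Of 213 values of lists, 189 kept direction and side of the threshold, 15 lost the call, 7 gained it and 2 changed direction. With no fold minimum, the fallen wound list at 24 hpa went to -0.00193 in fst; with only 2-fold members, the myoD 0 hpa list lower went to -0.19 in fst at 48 hpa. Calls were lost for the wound lists fallen at 6 hpa in myoD (0.0251 with no fold minimum, 0.10 for the 100 smallest p, 0.10 with an estimated correlation), fallen at 24 hpa in myoD (0.10, estimated), risen at 6 hpa in fst (0.27, estimated) and fallen at 24 hpa in fst (0.35 with the block, 0.34 estimated). Calls were gained with the preset correlation for those risen at 6 hpa in myoD (-0.10) and at 24 hpa in fst (-0.0706). Of the 0 hpa lists, that higher in fst lost its call in myoD at 6 hpa (0.0789 with 2-fold members, 0.11 estimated) and 24 hpa (0.22 with 2-fold members), that lower in myoD in fst at 0 hpa (-0.15 with 2-fold members) and, estimated, in myoD at 24 and 48 hpa (-0.15 and -0.12), and, estimated, that lower in fst at 24 hpa (-0.18) and that higher in myoD in fst at 48 hpa (0.17). Calls were gained for the fst list lower in myoD at 24 and 48 hpa (-0.37 and -0.34 with 2-fold members), and with the preset correlation for the fst list higher in myoD at 0 hpa (-0.0724) and the myoD list lower in fst at 6 hpa (-0.0703; also -0.0731 without fst 48 hpa replicate 1). With DESeq2, more than 1.5 times as many transcripts were lower in both at 0, 6 and 24 hpa (5, 4 and 21) and higher in both at 6 hpa (3); a call was gained for those lower at 0 hpa and higher at 6 hpa (unadjusted p = 0.000807 and 0.031), not for those lower at 6 hpa (0.0571).

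For transcripts given by identifier in a comparison, 850 of 909 values under alternatives kept direction and call, 59 were not past the threshold and 0 changed direction. At these depths, a transcript with 0 counts in a group is not shown to be absent.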

Other observations

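The classes of wound transcripts by time course were chosen after the data were seen, and so were their tests.

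Risen wound transcripts were parted by the time course in the controls of the other experiment into those that rose only early, those that rose early and were still raised at 48 hpa, and those that rose late. At 48 hpa after myoD RNAi, 40 of the 50 transcripts that rose early and stayed raised were lower than in control and 2 were higher, with a median log2 fold change of -1.03 (adjusted p = 1.25e-09, and 0.00125 with an estimated correlation). Of the 201 late transcripts, 63 were lower and 1 higher, with a median of -0.45 (adjusted p = 5.52e-08, and 0.00134 with an estimated correlation). These classes had changed from 0 hpa in the 10-feeding controls by medians of 1.32 and 0.65. Of the 28 that rose only early, which stood at a median of -0.02 in those controls, 1 was lower and 3 higher, with a median of 0.10 (adjusted p = 0.143). The fall of the early and lasting class was seen at 24 hpa too, with 29 of 50 lower and 0 higher and a median of -0.62 (adjusted p = 1.68e-07, and 0.00099 with an estimated correlation), and the 10-feeding controls had risen by a median of 1.31. Of the 201 late transcripts 7 were lower there, where those controls had changed by a median of only 0.26 (median difference -0.11, adjusted p = 0.0218, and adjusted p = 0.163 with an estimated correlation).

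After fst RNAi at 48 hpa, 19 of 61 early and lasting transcripts were lower and 0 higher (median -0.66, adjusted p = 1.2e-06), and 16 of 92 late transcripts were lower and 0 higher (median -0.56, adjusted p = 5.62e-10). Of 150 that rose only early, 2 were lower and 3 higher (median -0.15, adjusted p = 0.515). At 24 hpa after fst RNAi, 5 of the 61 early and lasting transcripts were lower and 0 higher (median -0.22, adjusted p = 0.0181, and adjusted p = 0.105 with an estimated correlation), and 2 of the 92 late ones were lower (median -0.13, adjusted p = 0.0248, and adjusted p = 0.125 with an estimated correlation). Of the 150 that rose only early, 4 were higher and 0 lower there (median 0.40, adjusted p = 0.0301, and adjusted p = 0.095 with an estimated correlation). In the 6-feeding controls the early and lasting, late and early classes had changed from 0 hpa by medians of 1.53, 0.49 and 0.00 at 24 hpa and 1.31, 1.12 and 0.10 at 48 hpa. The comparison at 24 hpa crosses the split of the libraries. The differences between the classes were not tested.

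At 6 hpa, the 238 transcripts that rose in the 10-feeding controls changed by a median of 0.11 in the 6-feeding controls and 0.43 after fst RNAi; the difference did not pass the test (adjusted p = 0.144, and 0.152 with an estimated correlation), and 46.6% of members had the smaller change after RNAi. Across 17288 transcripts, the change from 0 to 6 hpa in the 10-feeding controls had a Pearson r of 0.156 with that in the 6-feeding controls and 0.338 with that after fst RNAi, across transcripts that are not independent replicates. dd_Smed_v4_16222_0_1 was at 15.8 ± 2.43 and 17.9 ± 2.41 CPM in the 2 control groups at 6 hpa (SD, n = 3).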
